A study of Homo sapiens with 15 samples.

How the data were processed

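RNA was measured in A431 cells, an established human line from an epidermoid (squamous) carcinoma of the skin with an amplified EGFR gene. Per the labels' protocols, cells were reverse transfected with the lipid carrier Lipofectamine RNAiMAX and 20 nM of an antisense oligonucleotide (ASO), a short synthetic strand that binds a complementary RNA and can direct its cleavage, and RNA was collected after 48 h. The 15 libraries form 5 groups of 3: a scrambled control ASO, 2 ASOs against the long noncoding RNA (lncRNA) LINC00704 and 2 against the lncRNA LINC01116. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Libraries were QuantSeq 3′ mRNA-Seq V2 FWD, a kit that primes at the poly(A) tail and reads the 3′ ends of transcripts, sequenced paired-end on a NovaSeq X+ with 30 M reads planned per library.

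The authors' deposited table gives estimated counts, TPM and effective lengths for each of 243577 transcripts in each library. Per the submitters' processing notes, reads were quantified with Salmon 0.12.0 against hg38, and the transcript annotation release is not given in the sources used here. The deposited estimated counts are Salmon's split of reads among transcripts, so they need not be whole numbers, and reads that fit several transcripts or gene copies are shared among them by a model. The deposited TPM values divide by transcript length, which does not suit libraries that give about 1 tag per molecule whatever its length, so they served only as an alternative. The 15 columns of effective length were not used, and 0 columns belonged to other samples. Whether the quantification used the strand is not given in the sources used here, so antisense and overlapping genes are uncertain.

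Transcript identifiers were matched without version number to GENCODE 29 on hg38, and 202829 transcripts (83.3%) matched, 177066 of them with the same version. The transcripts that did not match held 5.54 to 6.20% of each library's estimated reads and stayed out of the gene tests. Estimated counts were summed over the transcripts of each of 58156 genes and rounded to whole numbers. LINC00704 carries the symbol MANCR in that annotation. The RefSeq model of LINC01116, a gene on the minus strand, extends from 176637609 down to 176611437 on chromosome 2, past the GENCODE 29 gene that ends at 176629589, so 3′ tags of such longer transcripts were not counted for LINC01116.

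Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with TMM scaling and edgeR's filterByExpr by group, which kept 11729 genes. One model with a term for each of the 5 groups was fitted to all 15 libraries, so the groups share 1 estimate of the spread. Each ASO was compared with the control, the mean of both ASOs of an lncRNA with the control, ASO 2 with ASO 1, and the mean of the LINC00704 ASOs with the mean of the LINC01116 ASOs. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and "rose" and "fell" are used only of called genes and lists. Genes called in both ASO tests of an lncRNA with the same sign were counted as changed alike. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over the 3 libraries of a group, and log2 changes carry the standard error (SE) of the fit. Intervals of target levels are the estimate ± 2 SE. A fold against a group in which every library is at 0 is a lower bound that sets the group at a floor of 3 counts over the group. Floors cover counting error only, since the reads are PCR copies counted without molecular identifiers, while the intervals of target levels rest on the fit's estimate of the spread between libraries.

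Of 29 gene lists, 25 had 5 or more tested members and were tested with camera (limma 3.58.1, voom) at a preset inter-gene correlation of 0.01, adjusted over the lists within each comparison. Camera with an estimated correlation and fry were run as checks. The gene lists, the groups, the tests and the rule for naming genes were fixed before the data were examined. The rule took, for each lncRNA, the 12 highest and 12 lowest log2 changes of the mean of both ASOs among genes called alike with at least 5 CPM over the 9 libraries concerned. It took the 4 highest and 4 lowest called genes of ASO 2 against ASO 1, the 6 highest and 6 lowest of LINC00704 against LINC01116, and up to 4 tested members with the smallest p from each list described. Genes without a symbol were skipped, at most 3 in any ranking. Some genes that the rule names are not reported here. Lists whose test was not called but which are described were chosen after their values were seen. These are the YAP and TEAD, EGFR and ERK, G2/M and 10p15 lists for the mean of the LINC00704 ASOs, and the heat shock and HOXD lists for LINC01116.

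Comparisons that share the 3 control libraries share their chance values. For each pair of such comparisons, 20 simulations drew every library, the controls included, from the control means. They gave the correlation, covariance and overlap that arise with no effect. The overlap of independent lists of the same sizes was computed as well. The control holds too few libraries to be split into parts of at least 2.

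The alternatives planned were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and library-size scaling, no filter and a stricter filter (1 CPM in at least 3 libraries), protein-coding genes only, a fit of only the groups compared, a block for the replicate number, adjusted p under 0.01, a 2-fold minimum, log2(TPM + 1) and log2(TPM + 0.1) with limma, and leaving out each library in turn. Chosen after seeing the data were a correction for gene length (a lowess trend, span 0.3, removed from each library through offsets), the same for length and GC content, leaving out replicates 2 and 3 of LINC00704 ASO 2, and treating both ASOs of an lncRNA as 1 group of 6 in all 15 libraries or in the groups compared alone. Other splits of the libraries were refitted, all 10 for each comparison of 3 with 3 and 100 drawn for the others. An earlier form of that test, which pooled both ASOs in 1 group of the 9 libraries, called 0 genes for LINC00704, and it was then rerun in the planned model of 15 libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

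The procedure was tested on simulated counts drawn from the real means and library sizes. For LINC00704 ASO 1 against control (11480 genes), 25.4% of genes changed 1.5-fold, 56.7% of genes changed 2-fold and 80.3% of genes changed 4-fold were called with the right sign, and 3.6% of called genes were unchanged. For the mean of both LINC00704 ASOs (11480 genes), the shares were 35.8, 68.7 and 86.4%, with 3.8% of called genes unchanged. For the mean of both LINC01116 ASOs, 0 genes were called with none changed (11480 genes). A planted list was found, with 0 of 50 random lists called (11482 genes). A planted length trend gave 1299 calls without the length correction and 0 with it (11476 genes). With the correction, 66.2% of genes changed 2-fold were called for LINC00704 ASO 1 against control (11476 genes).

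The libraries held 5.68 to 8.39 M estimated reads and 14435 to 15473 detected genes. LINC00704, at 18.6 ± 2.99 CPM (SD, n = 3) in the control, rested on 123 to 141 estimated reads per control library, so changes of low genes are known less well than those of abundant ones.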

Results

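Gene expression was measured in A431 cells 48 h after transfection with 20 nM of an antisense oligonucleotide (ASO). The series concerns lncRNAs needed for the growth of cutaneous squamous cell carcinoma, and its design asks how the transcriptome changes when LINC00704 or LINC01116 is targeted. The 15 libraries formed 5 groups of 3: a scrambled control ASO, LINC00704 ASO 1, LINC00704 ASO 2, LINC01116 ASO 1 and LINC01116 ASO 2. Replicates 1 to 3 held 7.81, 6.40 and 6.72 M estimated reads in the control, 8.39, 7.02 and 7.48 M in LINC00704 ASO 1, and 7.56, 7.75 and 7.15 M in LINC00704 ASO 2. They held 7.98, 6.73 and 5.68 M in LINC01116 ASO 1 and 7.70, 6.25 and 7.43 M in LINC01116 ASO 2.

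The targeted lncRNAs were read in every library before any other gene. LINC00704 (MANCR, ENSG00000231298.6, chromosome 10, 4650185 to 4678154 of hg38, minus strand) averaged 18.6 ± 2.99 CPM (SD, n = 3) in the control, with 15.2, 19.7 and 20.9 CPM in its libraries. It averaged 0.339 ± 0.471 CPM (SD, n = 3) with LINC00704 ASO 1, from 7, 0 and 1 estimated reads, and 7.84 ± 1.87 CPM (SD, n = 3) with LINC00704 ASO 2, at 6.54, 6.99 and 9.98 CPM. LINC00704 thus fell to 2.1% of the control with ASO 1 (interval 1.2 to 3.6%, edgeR adjusted p = 1.93e-07) and to 42.1% with ASO 2 (29.3 to 60.4%, adjusted p = 0.00377). The log2 change with ASO 1, −5.60, was −7.68 without LINC00704 ASO 1 replicate 1, beyond that interval. Its level was higher with ASO 2 than with ASO 1 by 4.35 ± 0.44 log2 units (SE, adjusted p = 2.83e-06). In the libraries labelled LINC01116 ASO 1 and ASO 2 it stood at 26.7 ± 1.43 and 23.3 ± 3.82 CPM (SD, n = 3), with log2 changes of 0.53 (adjusted p = 0.106) and 0.33 (adjusted p = 0.333).

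LINC01116 (ENSG00000163364.9, chromosome 2, 176629589 to 176637931, minus strand), a neighbour of the HOXD cluster, averaged 24.2 ± 0.634 CPM (SD, n = 3) in the control. It read 21.4, 16.8 and 18.3 CPM in the libraries labelled LINC01116 ASO 1 (18.8 ± 2.34, SD, n = 3) and 24.6, 25.4 and 18.7 CPM in those labelled LINC01116 ASO 2 (22.9 ± 3.61, SD, n = 3). These levels were 78.0% of the control (interval 60.7 to 100.2%, adjusted p = 0.141) and 94.4% (73.8 to 120.9%, adjusted p = 0.762), so neither passed the test. The difference with ASO 2, a log2 change of −0.08, became 0.04 without LINC01116 ASO 2 replicate 3 (adjusted p = 0.901). With a correction for gene length the log2 changes were −0.79 (adjusted p = 0.000943) and −0.46 (adjusted p = 0.0294), so the call depended on that choice, and it was also made on the TPM scales. The TPM values were not rescaled between libraries, and ZC3H13 and AKR1C1 shifted down on them as well. The call on TPM thus cannot be told from a shift of that scale. Longer RefSeq transcripts of this gene end outside the region counted. The target check thus did not settle the labels of these 6 libraries, which are called the libraries labelled LINC01116 ASO below. LINC01116 read 21.8 ± 1.35 and 29.4 ± 7.84 CPM (SD, n = 3) with LINC00704 ASO 1 and ASO 2, log2 changes of −0.15 (adjusted p = 0.591) and 0.28 (adjusted p = 0.289).

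**Figure D1:**
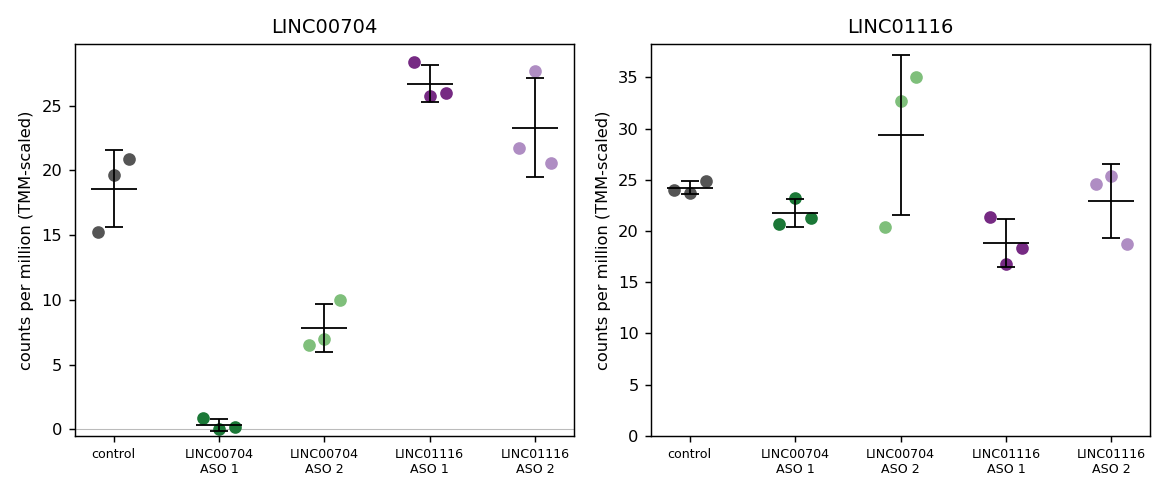
Levels of LINC00704 and LINC01116 in CPM (y axis, linear) in the 5 groups (x axis), with a point for each library and a bar for the mean ± SD of 3 libraries. LINC00704 lies between 0 and 0.877 CPM with its ASO 1 and between 6.54 and 9.98 CPM with its ASO 2, below the lowest control library at 15.2 CPM, while LINC01116 lies below the control libraries (at least 23.7 CPM) with its own ASO 1 (at most 21.4 CPM) and overlaps them with its ASO 2.

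The mean of both LINC00704 ASOs was compared with the control. The control was 1 oligonucleotide, so a change against it, in any ASO group, cannot be separated from an effect of that control. MX2 and PLCXD2, named below, also stood away from the control in the LINC01116 groups. MX2 read 3.49 and 2.33 CPM there against 11.8, and PLCXD2 13.3 and 12.8 against 5.63. Other named genes stood nearer the control there, such as LINC02551, at 4.54 and 3.91 against 3.21 CPM. The largest falls included genes of the antiviral interferon response. MX2, an interferon-induced GTPase (ENSG00000183486.12, chromosome 21, 41361943 to 41409390), fell from 11.8 ± 1.75 CPM in the control to 1.53 ± 0.362 with ASO 1 and 2.81 ± 2.01 with ASO 2 (SD, n = 3). IFI44L (ENSG00000137959.15, chromosome 1, 78619922 to 78646145) fell from 229 ± 28.8 to 29.7 ± 2.67 and 117 ± 7.37 CPM (SD, n = 3), a log2 change of −1.95 ± 0.10 (SE, adjusted p = 6.45e-09). RSAD2, which encodes the antiviral enzyme viperin, fell from 16.1 ± 0.983 to 4.36 ± 0.586 and 8.07 ± 0.470 CPM (SD, n = 3). HERC6, an interferon-induced ubiquitin ligase gene, fell as well (adjusted p = 0.00134). Other genes among the 12 lowest were FIGN (−1.36), the phospholipid flippase ATP11A (−1.27), TMEM63B (−1.23), AGAP1 and TMEM241 (−1.18), with adjusted p from 0.000354 to 0.00276.

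Among the 12 highest, ZC3H13, a component of the machinery that methylates adenosine in mRNA (ENSG00000123200.16, chromosome 13, 45954465 to 46052759), rose from 8.20 ± 5.05 CPM to 46.3 ± 5.58 with ASO 1 and 33.0 ± 11.9 with ASO 2 (SD, n = 3), a log2 change of 2.22 ± 0.30 (SE, adjusted p = 0.000281). SMAD3, a transducer of TGF-beta signals (ENSG00000166949.15, chromosome 15, 67063763 to 67195195), rose from 13.4 ± 2.03 to 51.0 ± 4.81 and 20.0 ± 0.874 CPM (SD, n = 3), by 1.26 ± 0.18 log2 units (SE, adjusted p = 0.000348). MLF1 (1.16), PLCXD2 (1.14) and the small nucleolar RNA host gene SNHG15 (1.11) rose too. So did the prolyl isomerase gene PPIA (1.09), whose many pseudogenes can share its reads. The small nucleolar RNA gene SNORD3A (1.51), the G protein regulator gene RGS2, the pseudogene SBDSP1, LINC02551 (1.02) and AZIN1 (1.01) were among the 12 as well. Each lost its call without control replicate 1, at adjusted p of 0.0543, 0.0791, 0.141, 0.0932 and 0.0933. Without control replicate 3 the adjusted p was 0.0629 for RGS2, 0.114 for SBDSP1, 0.0725 for LINC02551 and 0.0952 for AZIN1, and without LINC00704 ASO 1 replicate 2 it was 0.0583 for SBDSP1. On log2(TPM + 1) the ZC3H13 change was 0.33 (adjusted p = 0.455).

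In all, 2019 of 11729 genes were called for the mean of both LINC00704 ASOs, 1130 higher and 889 lower, and 178 of them changed at least 2-fold (62 higher and 116 lower). With scaling by library size alone 28.7% of calls were higher against 56.0%, and the median over all genes moved to −0.12, so directions are relative to the TMM scale. The count was 715 without control replicate 1, 993 without control replicate 3 and 3418 without LINC00704 ASO 2 replicate 1. With both ASOs as 1 group of 6, which counts the difference between the ASOs as spread, 519 genes were called in the 15 libraries and 0 in the 9 libraries compared, so every call named for this mean is lost there.

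Grouped by the gene lists, 25 of 40 tested interferon response genes fell and 1 rose (29 and 1 adjusted over the list alone), with a median log2 change of −0.63 (camera adjusted p = 6.76e-16, and adjusted p = 0.00203 with an estimated correlation). XAF1, an interferon-induced antagonist of apoptosis inhibitors, fell by 1.02 on the log2 scale. ISG15, a ubiquitin-like protein gene (ENSG00000187608.9, chromosome 1, 1001138 to 1014540), averaged 424 ± 23.6 CPM in the control, 143 ± 10.2 with ASO 1 and 392 ± 57.2 with ASO 2 (SD, n = 3). Its fall in the mean of both ASOs (−0.84, adjusted p = 4.27e-05) was not called with ASO 2 alone (adjusted p = 0.508). The member that rose was CXCL11, an interferon-induced chemokine gene (0.76, adjusted p = 0.00916), named after its values were seen.

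NF-kB and inflammatory cytokine genes moved the other way, 15 of 29 rising and 0 falling (15 and 0 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.62e-07, and 0.00358 with an estimated correlation). CXCL8, the neutrophil chemokine interleukin 8 (ENSG00000169429.10, chromosome 4, 73740506 to 73743716), averaged 6.998 ± 1.718 CPM in the control, 52.9 ± 1.57 with ASO 1 and 8.46 ± 2.36 with ASO 2 (SD, n = 3). CXCL1, a related chemokine (ENSG00000163739.4, chromosome 4, 73869393 to 73871242), averaged 43.3 ± 4.36, 200.3 ± 11.5 and 46.7 ± 6.40 CPM (SD, n = 3). The cytokine gene IL1A (1.03, adjusted p = 0.000589) and the mitochondrial superoxide dismutase gene SOD2 (0.60, adjusted p = 0.000841) rose as well. In LINC00704 ASO 2 alone 0 members rose and 3 fell, with a median of 0.00 (adjusted p = 0.701), so this average came from ASO 1. The 3 were RELB, TNFAIP3 and CSF1, named after their values were seen.

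Of 45 oxidative phosphorylation genes, 29 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 0.42, or 0.22 with length correction (camera adjusted p = 3.82e-12, but adjusted p = 0.409 with an estimated correlation). With ASO 1 alone 7 rose and 5 fell (10 and 5 adjusted over the list alone, median 0.12, adjusted p = 0.0972), so the list was not called there. SDHC, a subunit of succinate dehydrogenase (ENSG00000143252.14, chromosome 1, 161314257 to 161375340), averaged 603 ± 52.9 CPM in the control, 791 ± 58.0 with ASO 1 and 1038 ± 139 with ASO 2 (SD, n = 3). NDUFV2 of complex I, CYC1 of complex III and COX6C of complex IV rose by 0.78, 0.63 and 0.67 log2 units, and genes of this list often have processed pseudogenes that can share reads. Shorter genes were higher and longer genes lower in this comparison (Spearman −0.31 across genes, which are not independent replicates). Ribosomal protein genes took 8.60, 9.15 and 9.30% of reads in the control, 10.1, 10.5 and 9.54% with ASO 1, and 10.4, 13.4 and 15.1% with ASO 2. Mitochondrially encoded genes took 0.81 to 1.08% of reads in the control, 1.24 to 1.29% with ASO 1, above every control library, and 0.85 to 0.91% with ASO 2.

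Apoptosis regulators included 7 genes that rose and 1 that fell among 28 (9 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00223, but adjusted p = 0.168 with an estimated correlation). This average came from ASO 1, where 12 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.46, adjusted p = 8.23e-05, but 0.0506 with an estimated correlation). With ASO 2, 3 rose and 1 fell (3 and 1, median 0.10, adjusted p = 0.387). The list was lower with ASO 2 than with ASO 1 (8 lower and 3 higher, 9 and 3 adjusted over the list alone, median −0.28, adjusted p = 0.0113, but 0.128 with an estimated correlation and 0.116 without LINC00704 ASO 2 replicate 1). Its members act in both directions. BIRC3, an inhibitor of apoptosis, averaged 9.53 ± 3.91 CPM in the control, 36.0 ± 6.07 with ASO 1 and 14.6 ± 0.682 with ASO 2 (SD, n = 3), a log2 change of 1.25 (adjusted p = 0.000973). Another inhibitor, BIRC2 (0.49), and the death promoters BBC3 (0.93) and BIK (0.54) also rose, but without control replicate 1 their adjusted p was 0.0713, 0.05 and 0.0797, and without control replicate 3 that of BIK was 0.0921. BBC3 read 3.68 ± 0.430 CPM in the control, 12.5 ± 1.48 with ASO 1 and 3.93 ± 0.595 with ASO 2 (SD, n = 3). The death promoter BAD, named after its values were seen, read 13.6 ± 3.89 CPM in the control (SD, n = 3). It fell with ASO 1 (−2.42, adjusted p = 3.08e-05) and rose with ASO 2 (0.75, adjusted p = 0.0373). Its fall in the mean (−0.83, adjusted p = 0.0197) thus averages opposite directions.

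Lists of the keratinocyte's own structures were called lower in the mean, and each was called in 1 ASO group alone. Of 21 basal keratinocyte and hemidesmosome genes 7 fell and 2 rose (9 and 2 adjusted over the list alone, median −0.19), and of 32 epithelial junction genes 7 fell and 1 rose (8 and 1, median −0.19). Of 20 differentiation and cornified envelope genes 3 fell and 1 rose (6 and 1, median −0.33). ITGB4, the hemidesmosome integrin subunit (ENSG00000132470.13, chromosome 17, 75721328 to 75757818), fell from 81.7 ± 4.12 CPM to 45.8 ± 4.64 and 42.4 ± 9.58 (SD, n = 3). The anchoring collagen gene COL7A1 (−1.19), the epidermal regulators TP63 (−0.78) and GRHL1 (−0.90) and the catenin gene CTNNA1 (−0.55) fell as well, while the basal keratin gene KRT5 rose (0.45), with KRT14, named after its values were seen. KRT5 read 55.4 ± 5.82 CPM in the control, 95.0 ± 9.08 with ASO 1 and 60.7 ± 3.30 with ASO 2 (SD, n = 3). KRT14 read 43.1 ± 3.72, 71.1 ± 6.835 and 45.9 ± 5.46 CPM (SD, n = 3), so both keratin rises came mainly from ASO 1. In the differentiation list CALML3 and KLK10 fell with GRHL1 and KRT10 rose, and leaving out single libraries ended the calls of these 3 (CALML3 0.052 to 0.168, KLK10 0.0502 to 0.101, KRT10 0.0553 to 0.153), each for 6 or 7 of the 9 libraries. In the basal list 6 genes rose and 5 fell with ASO 1 (6 and 7 adjusted over the list alone, adjusted p = 0.894). With ASO 2, 0 rose and 10 fell (0 and 12, median −0.52, adjusted p = 1.34e-05, but 0.23 with an estimated correlation). The difference between ASOs was called (adjusted p = 0.000902, but 0.188 with an estimated correlation). In the junction list 4 rose and 3 fell with ASO 1 (4 and 4 adjusted over the list alone, adjusted p = 0.239). With ASO 2, 0 rose and 13 fell (2 and 14, median −0.33, adjusted p = 0.000221, but 0.23 with an estimated correlation). Its difference between ASOs (adjusted p = 0.0448, but 0.317 with an estimated correlation) was lost without LINC00704 ASO 1 replicates 1 or 3 or ASO 2 replicates 2 or 3 (0.0529 to 0.0894). In the differentiation list 0 rose and 7 fell with ASO 1 (0 and 7 adjusted over the list alone, adjusted p = 0.00895, but 0.0506 with an estimated correlation). With ASO 2, 1 rose and 2 fell (1 and 2, adjusted p = 0.504), and the difference was not called (adjusted p = 0.111). For the mean the camera adjusted p was 0.0245, 0.00548 and 0.0245 for these lists, but adjusted p = 0.512, 0.409 and 0.135 with an estimated correlation. With length correction the basal and junction lists were at 0.242 and 0.0833. All 3 calls were lost without control replicate 1 (0.0659, 0.0659 and 0.0899). The basal call was also lost without control replicate 2 (0.143) or LINC00704 ASO 2 replicate 3 (0.0681), and the differentiation call without LINC00704 ASO 2 replicate 1 (0.108), with scaling by library size alone and with no filter.

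Lists that went opposite ways with the LINC00704 ASOs were not called for their mean. Of 24 YAP and TEAD targets 5 rose and 2 fell (6 and 3 adjusted over the list alone), with a median of −0.09 while camera's direction was up (adjusted p = 0.949). The receptor kinase gene AXL (0.58) and AMIGO2 (0.45) rose, as did ANKRD1, AMOTL2 and F3, named after their values were seen. AXL read 17.8 ± 3.71 CPM in the control, 39.6 ± 2.80 with ASO 1 and 17.8 ± 1.97 with ASO 2 (SD, n = 3). AMIGO2 read 118 ± 10.3, 220 ± 4.45 and 117 ± 7.30 CPM (SD, n = 3), so both of these rises came from ASO 1. TEAD1 (−0.82) and CRIM1 (−0.45) fell, CRIM1 losing its call without control replicate 1 (0.0863) or 3 (0.0525). CRIM1 read 128 ± 11.1 CPM in the control, 128 ± 6.24 with ASO 1 and 68.9 ± 13.9 with ASO 2 (SD, n = 3), so its fall came from ASO 2. Of 25 EGFR and ERK outputs 3 rose and 3 fell (3 and 3 adjusted over the list alone, median 0.14, adjusted p = 0.762). The early response gene EGR1 fell (−0.63, adjusted p = 0.00305), with EGFR and the cyclin gene CCND1, while PHLDA2 rose with DUSP6 and ERRFI1, named after their values were seen. PHLDA2 read 93.2 ± 15.4 CPM in the control, 170.5 ± 1.71 with ASO 1 and 94.2 ± 4.15 with ASO 2 (SD, n = 3), so its rise came from ASO 1. CCND1 lost its call without any of 8 of the 9 libraries (0.0575 to 0.128), PHLDA2 without control replicate 1 (0.05), and EGFR (−0.34) without control replicates 1, 2 or 3 (0.128, 0.0541 and 0.0808) or LINC00704 ASO 1 replicate 1 (0.0566).

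Of 45 mitotic genes 3 rose and 7 fell in that mean (6 and 13 adjusted over the list alone, median −0.01, adjusted p = 0.453). The kinase gene NEK2 rose (0.45, adjusted p = 0.00645), with CDK1 and MAD2L1, named after their values were seen. The cytokinesis gene ECT2 fell (−0.34, adjusted p = 0.0082), as did the spindle genes TPX2 (−0.35) and KIF11 (−0.46). ECT2 read 202 ± 2.44 CPM in the control, 120.5 ± 4.54 with ASO 1 and 211 ± 24.3 with ASO 2 (SD, n = 3), so its fall came from ASO 1. Without control replicate 1 TPX2 and KIF11 were at 0.0722 and 0.0597, and without control replicate 3 KIF11 was at 0.067. Of 10 genes near LINC00704 in 10p15, 1 rose and 1 fell in that mean (1 and 1 adjusted over the list alone, median −0.00, adjusted p = 0.773), but the ASOs differed. With ASO 1, 6 fell and 1 rose (7 and 1 adjusted over the list alone, median −0.56, adjusted p = 0.0288, but 0.0804 with an estimated correlation and 0.0516 without control replicate 2). With ASO 2, 3 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.10, adjusted p = 0.28). The 3 were AKR1C1, AKR1C2 and AKR1C3, named after their values were seen, close paralogs that can share reads. Set against ASO 1, 6 were higher and 2 lower with ASO 2 (7 and 2 adjusted over the list alone, median 0.74, adjusted p = 0.00743, but 0.0526 with an estimated correlation). In the mean the transcription factor gene KLF6 rose (0.36), losing its call without control replicate 1 (0.0664), and the calmodulin-like gene CALML3 fell. KLF6 read 87.3 ± 3.32 CPM in the control, 167.8 ± 14.1 with ASO 1 and 74.95 ± 4.425 with ASO 2 (SD, n = 3). CALML3 read 20.35 ± 2.33, 9.60 ± 1.49 and 21.6 ± 3.59 CPM (SD, n = 3), so both changes came from ASO 1. CALML3 lost its call without any of 6 of the 9 libraries (0.052 to 0.168). On log2(TPM + 1) with limma the calls of AXL, AMIGO2, NEK2, KLF6, KRT5, BIRC3, BIRC2, BIK and AZIN1 in this comparison were lost.

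**Figure D2:**
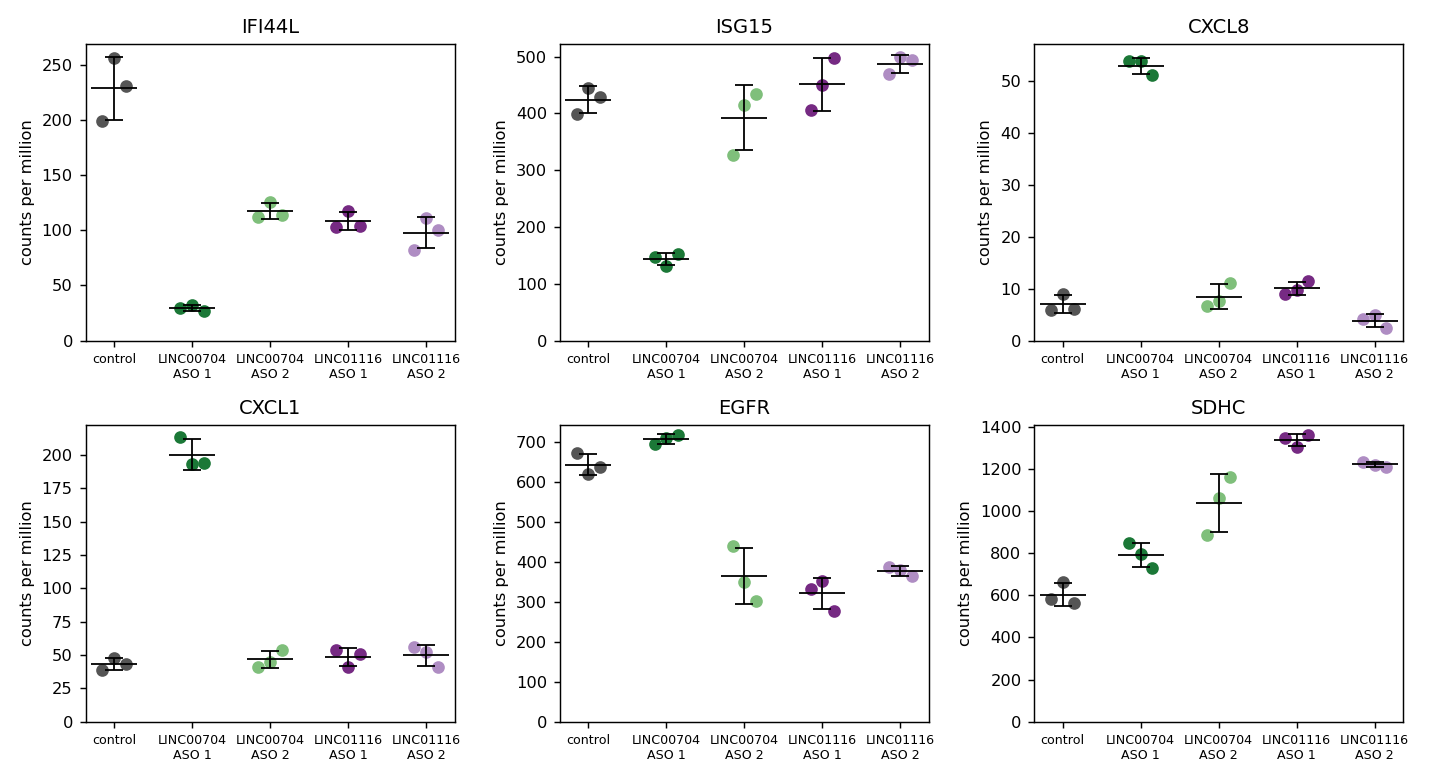
Levels of IFI44L, ISG15, CXCL8, CXCL1, EGFR and SDHC in CPM (y axes, linear, 1 panel per gene) in the 5 groups (x axes), with a point for each library and a bar for the mean ± SD of 3 libraries. IFI44L is below the control in all 4 ASO groups, and CXCL8 and CXCL1 are highest with LINC00704 ASO 1. EGFR is at 643 CPM in the control and 708 CPM with LINC00704 ASO 1. It is lower with LINC00704 ASO 2 (364 CPM) and in both LINC01116 groups (321 and 377 CPM).

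The LINC00704 ASOs were also compared with the control one at a time and with each other, to see where oligonucleotides against the same RNA part. With ASO 1, 17 of 29 NF-kB and cytokine genes rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 6.55e-15, and 0.000353 with an estimated correlation). YAP and TEAD target genes, which respond to cell tension and contact, included 10 that rose and 1 that fell among 24 (12 and 1 adjusted over the list alone, median 0.40, adjusted p = 8.23e-05, and 0.0469 with an estimated correlation). Outputs of EGFR and ERK signalling included 10 that rose and 1 that fell among 25 (12 and 1 adjusted over the list alone, median 0.34, adjusted p = 0.00204, but adjusted p = 0.0827 with an estimated correlation). Mitotic genes included 10 that fell and 0 that rose among 45 (12 and 1 adjusted over the list alone, median −0.18, adjusted p = 0.00348, but 0.0804 with an estimated correlation).

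With ASO 2 the NF-kB list was not called, nor were the mitotic genes, of which 16 rose and 4 fell (16 and 8 adjusted over the list alone, median 0.06, adjusted p = 0.387). Of the YAP and TEAD targets 9 fell and 0 rose (10 and 0 adjusted over the list alone, median −0.43, adjusted p = 1.34e-05, and 0.0413 with an estimated correlation). Of the EGFR and ERK outputs 7 fell and 0 rose (7 and 0 adjusted over the list alone, median −0.31, adjusted p = 0.0037, but adjusted p = 0.209 with an estimated correlation). EGFR itself, the growth factor receptor amplified in this line (ENSG00000146648.17, chromosome 7, 55019021 to 55211628), fell from 643 ± 26.1 to 364 ± 69.6 CPM with ASO 2 (SD, n = 3, adjusted p = 0.000927) and stood at 708 ± 11.9 CPM with ASO 1 (log2 change 0.14, adjusted p = 0.444). EGFR was about as low in the libraries labelled LINC01116 ASO 1 and ASO 2, at 321 ± 38.8 and 377 ± 11.6 CPM (SD, n = 3). Oxidative phosphorylation genes rose with ASO 2, 37 of 45 and 0 falling (39 and 0 adjusted over the list alone, adjusted p = 5.46e-21, but adjusted p = 0.209 with an estimated correlation). Their median was 0.69, or 0.28 with length correction. Interferon genes fell in both groups, 26 of 40 with ASO 1 and 1, CXCL11, rising (28 and 1 adjusted over the list alone, median −0.82, adjusted p = 1.34e-15), and 12 with ASO 2 and 0 rising (13 and 0, median −0.46, adjusted p = 2.93e-06). Both calls held with an estimated correlation (0.00108 and 0.0413). Gene length went with the change in ASO 2 (Spearman −0.46 across genes) and little in ASO 1 (−0.06).

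Set directly against each other, the ASO groups differed in 3382 genes, 1728 higher and 1654 lower with ASO 2 (51.1% higher, but 41.6% with scaling by library size alone and 58.4% with upper-quartile scaling). With ASO 2, 21 NF-kB and cytokine genes were lower and 0 higher (22 and 1 adjusted over the list alone, median −1.18, adjusted p = 8.5e-13), as were 18 of 24 YAP and TEAD targets (18 adjusted over the list alone, median −0.93, adjusted p = 1.04e-11) and 13 of 25 EGFR and ERK outputs (13, median −0.53, adjusted p = 7.77e-07). These 3 calls held with an estimated correlation (0.000592, 0.00219 and 0.0329). Mitotic genes were higher with ASO 2, 17 of 45 against 3 lower, CENPE, CENPF and ANLN, named after their values were seen (20 and 3 adjusted over the list alone, median 0.27, adjusted p = 0.000357, but 0.0526 with an estimated correlation). FXYD3, a regulator of the sodium pump (ENSG00000089356.18, chromosome 19, 35115879 to 35124324), was at 75.02 ± 29.46 CPM with ASO 2 and 8.30 ± 2.21 with ASO 1 (SD, n = 3), and BAD was at 23.0 ± 5.92 and 2.53 ± 0.544 CPM (SD, n = 3). IL1RL1, the receptor of interleukin 33, was at 1.84 ± 0.558 CPM with ASO 2 and 16.8 ± 4.06 with ASO 1 (SD, n = 3, log2 difference −3.19, adjusted p = 1.06e-05).

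The other named genes of this comparison varied more between libraries. ATP13A3, a polyamine transporter gene, was at 6.41 ± 5.61 CPM with ASO 2 and 148 ± 22.2 with ASO 1 (SD, n = 3), but at 31.2 ± 42.1 in the control, and its log2 difference of −4.54 was −3.95 without LINC00704 ASO 2 replicate 1 and −5.28 without replicate 2. AKAP9, a scaffold gene of the centrosome and Golgi, was lower with ASO 2 (−2.81, adjusted p = 0.00244), but its call was lost without ASO 2 replicates 2 and 3. HIST2H2AA4 was at 11.8 ± 5.16 CPM (SD, n = 3) and 0, at least 86.1-fold higher with ASO 2. It was not called by DESeq2, and it has an identical copy that can share its reads. NOMO3, a member of a near-identical family, and the antisense gene FRMD6-AS1 were called at adjusted p of 0.0456 and 0.0160, and both are uncertain. NOMO3 lost its call without any of 5 of the 6 libraries (0.0801 to 0.12), and FRMD6-AS1 without LINC00704 ASO 1 replicate 1 (0.0645), ASO 1 replicate 2 (0.0632) or ASO 2 replicate 3 (0.0822), with a log2 difference of 3.99 against 2.99 without ASO 1 replicate 3.

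ASO 1 alone gave 2231 calls (1153 higher and 1078 lower) and ASO 2 alone 2417 (1394 and 1023). The spread was estimated over all 5 groups, but the median gene variance was 0.0571 with ASO 2 and 0.0185 to 0.0242 in the other groups. Counts that involve ASO 2 thus rest on a spread below its own, and the fit of only the groups compared called fewer genes, as given below. With scaling by library size alone 35.6% against 51.7% of calls were higher for ASO 1 and 31.4% against 57.7% for ASO 2, where the median over all genes moved to −0.16. With upper-quartile scaling 43.4% of the ASO 1 calls were higher. The count for ASO 1 was 1402 without control replicate 1, 1415 without ASO 1 replicate 1 and 1446 without ASO 1 replicate 2. That for ASO 2 was 1359 without control replicate 1, 4027 without ASO 2 replicate 1, 1439 without replicate 2 and 1135 without replicate 3. The ASO 2 libraries stood apart from one another: a chi-square test of counts gave 23.0 and 42.5 per gene between replicate 1 and replicates 2 and 3, against 3.61 to 8.63 for every other pair of a group. Leaving replicates 2 and 3 out, an alternative added after this was seen, left 28 calls for ASO 2, 965 for the mean of both and 1548 between the ASOs.

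Both LINC00704 ASO tests called 535 genes with the same sign, 313 higher and 222 lower, and 162 with opposite signs. Independent lists of these sizes would share 137 higher and 94 lower genes and oppose in 229. Simulated unchanged groups that shared a simulated control had 0 in common on average. The log2 changes correlated at 0.339 across genes, below the 0.499 that simulated unchanged groups give through the shared control, and their covariance was 0.128 against 0.0660 simulated, a difference of 0.0617. Part of the excess overlap may come from the shared control libraries. The count of 535 was 188 without control replicate 1, 267 without control replicate 3, 320 and 318 without ASO 1 replicates 1 and 2, 332 and 279 without ASO 2 replicates 2 and 3, and 13 without both of the latter.

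Both groups of libraries labelled LINC01116 ASO were compared with the control. HSP90B1, the chaperone of the endoplasmic reticulum also called GRP94 (ENSG00000166598.14, chromosome 12, 103930107 to 103953645), fell from 392 ± 84.5 CPM in the control to 16.3 ± 8.08 and 7.16 ± 0.738 in the ASO 1 and ASO 2 groups (SD, n = 3), a log2 change of −5.16 ± 0.24 (SE, adjusted p = 1.69e-10). VPS37B, a subunit of the ESCRT-I sorting complex (ENSG00000139722.6, chromosome 12, 122865328 to 122896444), fell from 212 ± 9.21 to 32.1 ± 1.76 and 29.3 ± 6.20 CPM (SD, n = 3). INO80B, of the INO80 chromatin remodeller (ENSG00000115274.14, chromosome 2, 74455023 to 74457960), fell from 86.3 ± 7.49 to 14.4 ± 2.41 and 16.2 ± 0.365 CPM (SD, n = 3). TAF3, a subunit of the general transcription factor TFIID (ENSG00000165632.7, chromosome 10, 7818504 to 8016627), stood at 42.2 ± 1.72 CPM in the control (SD, n = 3) and at 0 in all 6 libraries, at least 535.9-fold lower (adjusted p = 0.0015). TAF3 also read 42.96, 0 and 0 CPM in the LINC00704 ASO 1 libraries and 0, 29.55 and 23.24 in those of ASO 2. Its level thus switched between replicates of the same group, and its fold is uncertain.

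The other falls among the 12 lowest were the importin gene IPO5 (−6.28), RBM41 (from 15.6 ± 2.58 to 1.36 ± 1.17 CPM with ASO 1, SD, n = 3, and 0 in every ASO 2 library), the chaperone gene DNAJC10 (−6.09), the NF-kB subunit gene NFKB1 (−3.26) and the kinase gene VRK1 (−2.50), with EIF3C, MATR3 and GTF2IP1, which have near-identical or overlapping records and are uncertain. Leaving out 1 library moved some of these by over 1.5 times. IPO5 went to −6.90 without LINC01116 ASO 1 replicate 2 and −7.27 without ASO 2 replicate 2, and DNAJC10 to −6.78 without ASO 1 replicate 1 and −7.02 without ASO 2 replicate 2. EIF3C went from −4.56 to −5.25 without ASO 1 replicate 1 and −5.42 without ASO 2 replicate 3, NFKB1 to −6.79 without ASO 1 replicate 1, and VRK1 to −4.86 without ASO 1 replicate 3. DNAJC10 was not called by limma-voom. At the level of transcript records the falls were more frequent, 461 of 11929 named transcripts falling at least 4-fold and 58 rising, against 35 and 1 of 8828 genes.

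Among the 12 highest, CENPX, a centromere protein gene (ENSG00000169689.14, chromosome 17, 82018702 to 82024107), rose from 18.4 ± 2.84 to 55.1 ± 6.81 and 46.8 ± 7.42 CPM (SD, n = 3), by 1.46 ± 0.18 log2 units (SE, adjusted p = 1.16e-05). UQCC2, an assembly factor of respiratory complex III (ENSG00000137288.9, chromosome 6, 33694293 to 33711727), rose from 30.0 ± 2.89 to 82.0 ± 1.85 and 71.4 ± 4.91 CPM (SD, n = 3). ADSL of purine synthesis (1.36), the methyltransferase gene EEF1AKMT1 (1.33), ALKBH7 (1.31) and NPRL2, of a complex that restrains mTORC1 (1.29), rose too. FKBP1A (2.53) moved to 3.36 without control replicate 3 and the lncRNA CASC9 (1.62) to 2.50 without control replicate 2. ZC3H13 (1.36) reversed to −0.62 on log2(TPM + 1), and the histone gene HIST1H4J (1.46), BOLA2B (1.46, not called on the TPM scales) and the antisense gene LINC01589 (1.40) can share reads with copies or overlapping genes and are uncertain.

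By list, 39 of 45 oxidative phosphorylation genes rose and 1 fell (39 and 1 adjusted over the list alone), with a median of 0.74, or 0.33 with length correction (camera adjusted p = 4.3e-17, but adjusted p = 0.252 with an estimated correlation). SDHC rose from 603 ± 52.9 to 1338 ± 28.6 and 1221 ± 12.1 CPM (SD, n = 3), and COX6B1 (0.91), NDUFS3 (0.93) and ATP5MC3 (0.74) rose with it, the last not called on log2(TPM + 1). The member that fell was the complex I gene NDUFS1 (−0.60), named after its values were seen. Ribosomal protein genes took 12.7 to 13.6% of reads in these 6 libraries against 8.60 to 9.30% in the control. Mitochondrially encoded genes took 0.71 to 0.78%, below every control library (0.81 to 1.08%), and the Spearman correlation of change with gene length was −0.43 across genes.

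Interferon response genes fell here too, 18 of 40 with 1 rising (19 and 1 adjusted over the list alone), with a median of −0.34 (camera adjusted p = 0.00126, but adjusted p = 0.157 with an estimated correlation). IFI44L fell from 229 ± 28.8 to 108 ± 8.20 and 98.0 ± 14.4 CPM (SD, n = 3), and XAF1 (−1.07), the RNA sensor gene IFIH1 and the antiviral tether gene BST2 (−0.88) fell as well, while IFI6 rose (0.34, named after its values were seen). Of 32 epithelial junction genes 13 fell and 1 rose (13 and 1 adjusted over the list alone, median −0.20, adjusted p = 0.0101, but 0.396 with an estimated correlation). The tight junction gene CLDN1 (ENSG00000163347.5, chromosome 3, 190305701 to 190322475) fell from 199.6 ± 30.5 to 95.4 ± 8.06 and 95.5 ± 7.41 CPM (SD, n = 3), with TJP1 (−1.17) and CTNND1 (−0.96), whereas CLDN4 rose (0.60, named after its values were seen). Of 24 YAP and TEAD targets 9 fell and 0 rose (9 and 0 adjusted over the list alone, median −0.21). Camera's adjusted p for that list was 0.0101, but 0.198 with an estimated correlation. The targets that fell included MYOF (−1.30), the transcription factor gene TEAD1 (−1.08), FJX1 (−0.90) and CRIM1 (−0.78). With length correction the junction and YAP lists were at adjusted p of 0.199 and 0.098.

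Of 31 NRF2 antioxidant genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.25, adjusted p = 0.0101, but 0.157 with an estimated correlation and 0.0723 with length correction). The 1 that fell was NFE2L2, which encodes NRF2 itself (from 184 ± 40.0 to 88.5 ± 7.35 and 73.0 ± 8.78 CPM, SD, n = 3). NQO1 (0.58), AKR1C2 (0.73) and AKR1C1 (0.84) rose, though on log2(TPM + 1) they were at 0.08 (adjusted p = 0.489), 0.06 (0.61) and −0.37 (0.176). Of 29 cholesterol synthesis genes 8 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.20, adjusted p = 0.0203, but 0.157 with an estimated correlation). That call was lost with scaling by library size alone. FDFT1 (0.73), ACAT2 (0.67) and EBP (0.58) rose on the count scale but were not called on log2(TPM + 1). CYP51A1 was among those that fell (−0.21, named after its values were seen). Heat shock genes were not called as a list (median −0.18, adjusted p = 0.22), although 8 of 20 fell and 2 rose (8 and 2 adjusted over the list alone). HSPH1 (−0.94), HSPD1 (−0.86) and CHORDC1 (−0.61) fell, HSPA8 rose (0.61) but was not called on log2(TPM + 1), and HSPE1 rose, named after its values were seen.

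Genes around LINC01116 were tested as a group. Of 11 tested HOXD neighbours 1 rose and 2 fell (1 and 2 adjusted over the list alone), the median was 0.13 while camera's direction was down, and the list was not called (adjusted p = 0.902). HAGLROS, a lncRNA of the cluster, rose from 0.602 ± 0.149 to 2.29 ± 0.473 and 1.63 ± 0.546 CPM (SD, n = 3), LNPK (−0.72, adjusted p = 8.32e-05) and NFE2L2 fell, and MTX2 was at 0.19 (adjusted p = 0.15). In all, 4405 genes were called for the mean of both groups, 2070 higher and 2335 lower, and 764 changed at least 2-fold (199 higher and 565 lower). The groups labelled ASO 1 and ASO 2 gave 3947 (1865 and 2082) and 3770 calls (1822 and 1948) one at a time. With scaling by library size alone 29.5% of calls were higher against 47.0% for the mean, 32.8% against 47.3% for ASO 1 and 26.9% against 48.3% for ASO 2, and the medians over all genes moved to −0.15, −0.15 and −0.14. With upper-quartile scaling 55.4, 57.2 and 55.4% were higher, so the balance of higher and lower calls turned.

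**Figure D3:**
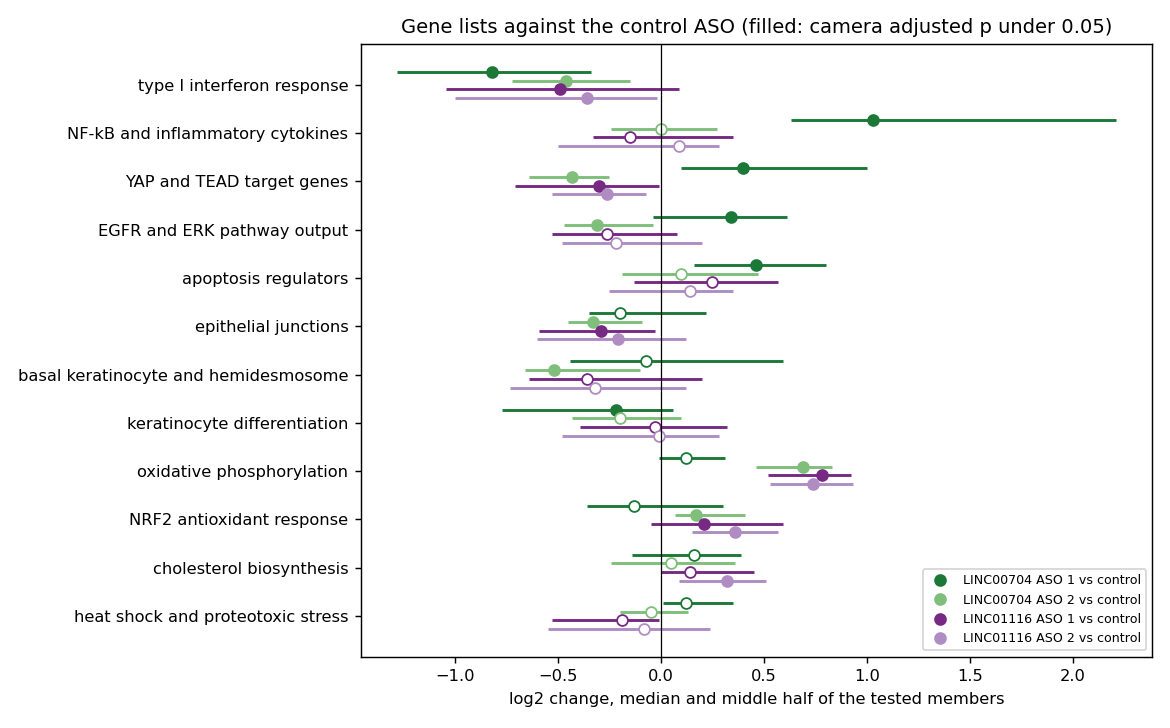
Median log2 change of 12 gene lists (points, x axis, with bars for the middle 50% of members) in each of the 4 ASO groups against the control, filled where camera's adjusted p is under 0.05. The interferon medians lie left of 0 and are filled in all 4 groups. The NF-kB list is filled with LINC00704 ASO 1 alone (median 1.03), and oxidative phosphorylation is filled right of 0 with LINC00704 ASO 2 (0.69) and both LINC01116 groups (0.78 and 0.74). With an estimated correlation the interferon calls of the LINC01116 groups (adjusted p = 0.265 and 0.118) and all 3 oxidative phosphorylation calls (adjusted p = 0.209, 0.281 and 0.268) were lost.

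**Figure D4:**
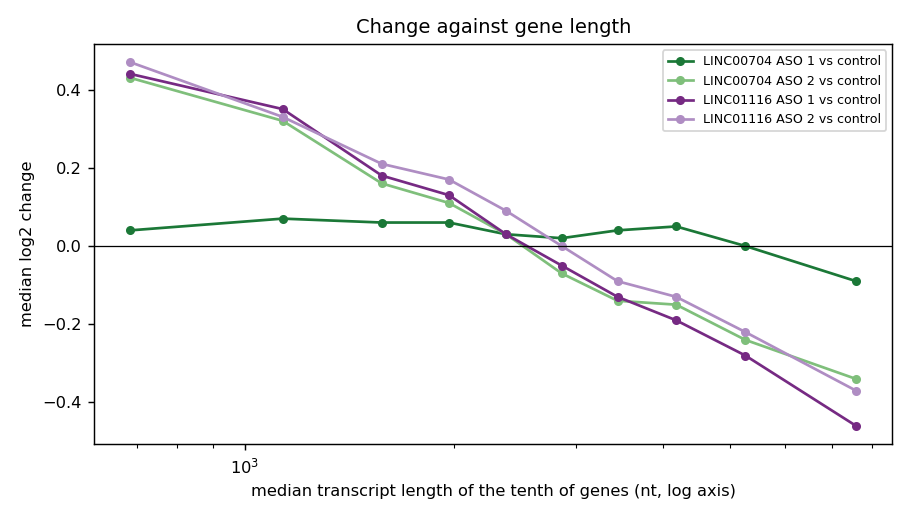
Median log2 change against the control (y axis) in 10 equal parts of the tested genes ordered by gene length, plotted at the median length of each part in nucleotides (x axis, log scale), with a line for each ASO group. The line of LINC00704 ASO 1 is nearly flat, from 0.04 in the shortest genes through at most 0.07 to −0.09 in the longest, while those of LINC00704 ASO 2 (0.43 to −0.34), LINC01116 ASO 1 (0.44 to −0.46) and LINC01116 ASO 2 (0.47 to −0.37) fall with length.

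Both LINC01116 ASO tests called 2810 genes with the same sign, 1311 higher and 1499 lower, and 0 with opposite signs, where independent lists would share 290 and 346 and oppose in 633. The log2 changes correlated at 0.746 across genes, against 0.494 in simulated unchanged groups, with a covariance of 0.442 against 0.0670 simulated, a difference of 0.375. Part of the excess may come from the shared control libraries. Set directly against each other, the LINC01116 ASO groups differed in 0 genes by edgeR's test, with 1869 genes at an unadjusted p under 0.05, 206 genes by DESeq2 (31 higher and 175 lower with ASO 2), and 5 with RLE scaling or with the length correction. The edgeR count was 7 without LINC01116 ASO 1 replicate 3 and 71 without LINC01116 ASO 2 replicate 1. It was also higher in the fit of only the groups compared, as given below. Apoptosis regulators were lower with ASO 2 as a list (median −0.18, 0 of 28 called over all genes and 1 lower adjusted over the list alone, camera adjusted p = 0.0328, but 0.554 with an estimated correlation). That call was lost without LINC01116 ASO 1 replicate 1 (0.0613), ASO 2 replicate 1 (0.0661) or ASO 2 replicate 3 (0.0665).

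The mean of the LINC00704 ASOs was set against the mean of the LINC01116 ASO libraries, a comparison in which the control cancels. NF-kB and cytokine genes were higher with the LINC00704 ASOs, 18 of 29 and 0 lower (19 and 1 adjusted over the list alone, median 0.46, adjusted p = 9.9e-06, and 0.0179 with an estimated correlation), as were 14 of 24 YAP and TEAD targets (16 adjusted over the list alone, median 0.38, adjusted p = 0.000368, but 0.0991 with an estimated correlation). Both differences came mainly from LINC00704 ASO 1. Against the control the NF-kB median was 1.03 with LINC00704 ASO 1, 0.00 with ASO 2 and −0.15 with LINC01116 ASO 1. The YAP and TEAD median was 0.40 with LINC00704 ASO 1 but −0.43 with ASO 2, so that mean averages opposite directions. Oxidative phosphorylation genes were lower, 29 of 45 against 2 higher, NDUFB9 and NDUFS1, named after their values were seen (30 and 3 adjusted over the list alone, median −0.37, adjusted p = 7.37e-08, but 0.357 with an estimated correlation). Their median against the control was 0.12 with LINC00704 ASO 1 but 0.69 with ASO 2, near the 0.78 with LINC01116 ASO 1. This difference thus came mainly from LINC00704 ASO 1. Of the 10p15 genes 7 of 10 were lower and 2 higher, KLF6 and NET1, named after their values were seen (7 and 2 adjusted over the list alone, median −0.49, adjusted p = 0.037, but 0.131 with an estimated correlation and 0.0702 with length correction). Against the control the 10p15 median was −0.56 with LINC00704 ASO 1, 0.10 with ASO 2 and 0.27 with LINC01116 ASO 1. HSP90B1 was higher by 5.11 ± 0.22 log2 units (SE, adjusted p = 4.62e-11), and IPO5 (6.58) and DNAJC10 (4.80) were higher too. So were RBM41 (adjusted p = 5.98e-05) and the heat shock cochaperone gene DNAJB1 (adjusted p = 0.000744), for which no fold is given because 1 LINC01116 group was at 0 throughout. DNAJB1 read 17.2 ± 4.14 and 10.2 ± 7.63 CPM in the LINC00704 ASO 1 and ASO 2 groups against 0 and 4.88 ± 5.31 in the LINC01116 groups, and RBM41 read 19.4 ± 2.81 and 5.51 ± 4.97 CPM against 1.36 ± 1.17 and 0 (SD, n = 3). TAF3 was at least 202.7-fold higher (adjusted p = 0.00592), although TAF3 was also at 0 in 3 of the 6 LINC00704 ASO libraries. LINC00704 itself was lower (−3.85), with the centromere gene CENPP (−1.81), the channel gene PANX2 (−1.68) and FXYD3 (−1.64). The mitochondrial tRNA synthetase gene FARS2 (−1.60, adjusted p = 1.24e-07) and HNRNPF (−2.08, adjusted p = 0.0371), which has pseudogenes, were lower too. CENPP averaged 0.752 and 8.06 CPM with LINC00704 ASO 1 and ASO 2, against 9.23 and 8.56 in the LINC01116 groups. In the same order PANX2 averaged 1.17 and 9.22 CPM against 10.96 and 10.4, and FXYD3 8.30 and 75.02 against 84.89 and 70.57. The differences of CENPP, PANX2 and FXYD3 thus came mainly from LINC00704 ASO 1. FARS2 averaged 3.18 and 15.97 CPM against 20.31 and 23.43.

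This comparison called 4460 genes, 2408 higher and 2052 lower with the LINC00704 ASOs, and with upper-quartile scaling 40.3% of calls were higher against 54.0%, with a median of −0.11 over all genes. TAF3 lost its call without LINC00704 ASO 1 replicate 1 (adjusted p = 1), as it did with limma-voom, on log2(TPM + 1) and without LINC00704 ASO 2 replicates 2 and 3. DNAJC10 lost its call with limma-voom. HNRNPF lost it without any of 7 libraries (0.0576 to 0.132), and also with DESeq2, limma-voom, only the groups compared, the replicate block, both TPM scales, without LINC00704 ASO 2 replicates 2 and 3, and with both ASOs as 1 group of 6. IPO5 moved to 7.20 and 7.57 without LINC01116 ASO 1 replicate 2 and ASO 2 replicate 2, DNAJC10 to 5.50 and 5.73 without ASO 1 replicate 1 and ASO 2 replicate 2, and LINC00704 to −4.89 without LINC00704 ASO 1 replicate 1. CENPP, PANX2 and FXYD3 were not called with both ASOs as 1 group of 6, nor was DNAJB1 where that fit used only the groups compared. The changes of both lncRNAs against the control correlated at 0.529 across genes, against 0.661 in simulated unchanged groups, with a covariance of 0.191 against 0.0663 simulated, a difference of 0.125. They shared 792 higher and 510 lower genes, where independent lists would share 199 and 177, and part of this may come from the shared control libraries.

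Most markers of other cell types were low, but not all. For reference, the keratin genes KRT18, KRT5 and KRT14 read 199 ± 19.6, 55.4 ± 5.82 and 43.1 ± 3.72 CPM in the control, and EGFR 643 ± 26.1 CPM (SD, n = 3). Of 10 fibroblast markers FBLN1 read 29.3 ± 2.47 and LUM 4.85 ± 1.08 CPM there, and COL1A2, COL3A1, PDGFRA and COL6A3 had 0 reads in every library. Of 11 immune markers CD68, a lysosomal protein gene, read 15.1 ± 1.33 CPM in the control and 6.07 ± 1.04 with LINC00704 ASO 1, and PTPRC, CD3E and MS4A1 had 0 reads. The endothelial cadherin gene CDH5 read 0.3214 ± 0.2996 CPM in the control and 3.19 ± 1.41 with LINC00704 ASO 1 (SD, n = 3), while KDR and CLDN5 had 0 reads. Of 8 melanocyte markers MITF read 13.8 ± 1.87 CPM in the control and 20.0 ± 2.52 with LINC00704 ASO 1 (SD, n = 3), while MLANA, TYR and SOX10 had 0 reads.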

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

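The tests of gene length variance, of the length correction for the 35 genes and of the correlation with the LINC00704 ASO 2 replicates were written before their results were seen, and all other tests of this section, the splits included, were chosen after.

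The LINC00704 ASOs differed from each other by a direct test in 3382 genes, which marked the difference between groups. The median log2 difference of ASO 2 against ASO 1 was −1.18 for NF-kB and inflammatory cytokine genes, −0.93 for YAP and TEAD targets and −0.53 for EGFR and ERK outputs. The 10 splits of these 6 libraries are too few for a share under 0.05, and 1 of the 10 gave as many genes as the real split, the real split itself, the highest other calling 1. The same held for ASO 1 against control (2231 genes, highest other 1) and ASO 2 against control (2417 genes, highest other 1). Nothing measured here separates loss of LINC00704 from effects of each oligonucleotide alone, so the differences are given as values.

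LINC00704 ASO 2 replicate 1 stood apart from replicates 2 and 3. A control library under a wrong label would hold LINC00704 at the control level, but replicate 1 held 6.5 CPM against at least 15.2 in the control. Depth differed little, 7.56 M reads in replicate 1 and 7.75 M in the deeper of the other libraries. The median gene variance in this group was 2.97 times that of the other groups before a length correction and 2.48 times after it, so a length trend may carry part of the spread but not all of it. A difference in transfection or in the state of the cells was not tested, since nothing in the labels records one.

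For the mean of both LINC00704 ASOs, 3 of 100 drawn splits, the real one included, called as many genes as the real one. The others mixed libraries of different groups or exchanged whole groups, and their median was 0 genes. The libraries of these 3 groups were thus not exchangeable, but the count does not show that the control in particular stood apart. The real split called 2019 and the highest other 3210, and for genes changed alike 4 of 100 splits reached the real 535, the highest other giving 1272. That highest split took the 3 ASO 2 libraries as the control, which points to a structure of the samples, the distance of ASO 2 from the other groups, as large as that between ASOs and control.

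The libraries labelled LINC01116 ASO differed from the LINC00704 ASO libraries in 4460 genes by a direct test, with a median difference of 0.46 for NF-kB and inflammatory cytokine genes, which marked a difference between groups. The NF-kB difference came mainly from LINC00704 ASO 1, whose median against the control was 1.03. That of LINC00704 ASO 2 was 0.00 and that of LINC01116 ASO 1 −0.15. Between the lncRNAs 1 of 100 splits, the real one, called as many genes, the highest other calling 2868. The same held for both LINC01116 ASO groups against the control (4405 genes, 1 of 100, highest other 4237). It held for genes changed alike as well (2810, 1 of 100, highest other 2785). The other splits had a median of 0 genes, so these libraries too were not exchangeable, which is all that such splits show. The highest other splits for LINC01116 kept the 3 controls together and mixed the ASO libraries. For each group alone, 10 splits are too few for a share under 0.05: 1 of 10 reached the 3947 of ASO 1 and 1 of 10 the 3770 of ASO 2, the highest other calling 0 in each case. Between them, 10 of 10 splits called at least the real 0 of edgeR's test, the highest other 1 (1869 genes had an unadjusted p under 0.05, and DESeq2 called 206).

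Short genes were higher and long genes lower in the libraries labelled LINC01116 ASO. Gene length cannot be the whole of the change, since 2903 of the 4405 genes were called both with and without a length correction. Exchange with the LINC00704 ASO libraries was excluded, the lowest LINC00704 level in the LINC01116 libraries being 20.5 CPM against 15.2 in the lowest control library. The difference of LINC00704 ASO 2 replicates 2 and 3 from replicate 1 correlated with the LINC01116 change at 0.223 (Pearson) and 0.366 (Spearman) across genes, which leaves undecided whether a state shared with those libraries might contribute. The biological explanation, loss of LINC01116, stays open, since the target check was undecided.

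Transcripts that fell over 4-fold in the libraries labelled LINC01116 ASO came from 424 genes, whose sums had a median log2 change of −0.54, and 77.1% of these sums fell by less than 2-fold or rose. Reads may thus have moved between transcript records of the same gene, an explanation found and tested on the same data. Of the unnamed transcripts 10 rose over 4-fold and 40 fell, a count of records that does not show where the reads went. Adding 1 unnamed transcript evened out 16 of the 35 genes that fell over 4-fold, and subtracting 1 evened out 19. Subtracting matches records that fell with the gene, and more unnamed records fell than rose, so this comparison cannot exclude a single mirror transcript. After the length correction 94.3% of the 35 genes were still called, but this could not test length bias. From the shortest to the longest of 10 equal parts of the genes, the median log2 change ran only from 0.44 to −0.46 with LINC01116 ASO 1. With LINC01116 ASO 2 it ran from 0.47 to −0.37. Removing such a trend could hardly undo a called 4-fold fall.

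The gene tests did not use transcripts without a gene name here, of which 774 passed the filter with a mean of at least 5 CPM. Of these, 44 passed the threshold for the mean of both LINC00704 ASOs and 226 for the libraries labelled LINC01116 ASO. Of the 11729 tested genes, which include lower ones, 2019 and 4405 were called, a larger share in both comparisons. The unnamed transcripts that passed lie outside the genes compared, and no biological explanation was tested for them.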

How the results depend on the processing

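Most results kept their direction and their side of the threshold. Of the values of named genes and lists, 1581 were the same and 99 lost their call when 1 library was left out. Under the other settings 2748 were the same, 318 lost their call and 4 reversed. Of the results of whole comparisons, 192 were the same, 32 moved and 1 reversed when 1 library was left out, and under the other settings 332 were the same, 3 lost their call, 14 gained one and 89 moved. Where no construction is named below, the cause was not tested. At 5.68 to 8.39 M reads per library a gene at 1 CPM rests on fewer than 10 reads, which limits results for low genes.

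Leaving out each library in turn gave 1402 to 1800 genes for LINC00704 ASO 1 (2231 with all), 1135 to 4027 for ASO 2 (2417) and 715 to 3418 for both (2019). Leaving 1 library out gave 188 to 757 genes changed alike for LINC00704 (535) and 0 to 71 for LINC01116 ASO 2 against ASO 1 (0 by edgeR, 1869 at an unadjusted p under 0.05). The LINC01116 change with ASO 2 ranged from −0.16 to 0.04. Lists called ranged from 4 to 7 for both LINC00704 ASOs and from 0 to 1 for LINC01116 ASO 2 against ASO 1. Correlations across genes between ASO 1 and ASO 2 were 0.30 to 0.44 for LINC00704 (0.34 with all) and 0.69 to 0.75 for LINC01116 (0.75), and 0.50 to 0.59 between the lncRNAs (0.53).

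A 2-fold minimum, which by construction keeps fewer genes, left 528 for LINC00704 ASO 1, 215 for ASO 2, 178 for both, 849 for ASO 2 against ASO 1, 836, 739 and 764 for LINC01116 ASO 1, ASO 2 and both, 551 between the lncRNAs, and 25 and 432 changed alike for LINC00704 and LINC01116. An adjusted p under 0.01 left 1080, 1142 and 758 for LINC00704 ASO 1, ASO 2 and both, 1939 for ASO 2 against ASO 1, 2403 for LINC01116 ASO 2, 2890 between the lncRNAs, and 129 and 1853 changed alike.

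For LINC01116 ASO 2 against ASO 1, DESeq2 called 206 genes, RLE, upper-quartile and protein-coding settings and the length correction 5 each, library size 6, no filter 563 and the fit of only the groups compared 190. DESeq2 gave correlations of 0.33 and 0.77 between ASOs of LINC00704 and LINC01116 and 0.51 between the lncRNAs. In the same order limma-voom gave 0.32 and 0.78 for the ASOs, no filter 0.46, 0.58 and 0.62, the stricter filter 0.35 and 0.73 for the ASOs, protein-coding genes 0.34 and, between the lncRNAs, 0.54, and only the groups compared 0.31 and 0.82. Only the groups compared also gave 752, 1308 and 2159 genes for LINC00704 ASO 2, both and ASO 2 against ASO 1, and 301 alike.

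Camera with an estimated correlation called 3, 2 and 2 lists for LINC00704 ASO 1, ASO 2 and both (11, 7 and 7 at the preset), 3 for ASO 2 against ASO 1 (13), 0 for LINC01116 ASO 1, ASO 2, both and ASO 2 against ASO 1 (5, 6, 6 and 1), and 1 between the lncRNAs (5). Fry called 21 for LINC00704 ASO 2 against ASO 1, 17, 17 and 18 for LINC01116 ASO 1, ASO 2 and both, 0 for ASO 2 against ASO 1, and 19 between the lncRNAs. Other numbers of lists called between LINC01116 ASO 2 and ASO 1 were 2 with library size, 2 with no filter and 3 with only the groups compared, and no filter gave 10 between the lncRNAs.

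The LINC01116 level was called where the planned test did not call it. With the length correction its log2 changes were −0.79, −0.46 and −0.62 for ASO 1, ASO 2 and both, with length and GC content −0.77, −0.51 and −0.64, on log2(TPM + 0.1) −1, −0.77 and −0.89, and on log2(TPM + 1) −0.91, −0.71 and −0.81. With library size it was −0.50 for ASO 1 and −0.38 for both. The TPM values were not rescaled between libraries, and ZC3H13 and AKR1C1 shifted down on them as well.

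The length correction, chosen after seeing the data, gave 1429 genes for LINC00704 ASO 2, 3 lists for both LINC01116 ASOs and correlations of 0.35, 0.72 and 0.49. Length with GC content gave 1215 genes for LINC00704 ASO 2, 301 alike, 4 lists for both LINC00704 ASOs, 0 for LINC01116 ASO 2 against ASO 1, and correlations of 0.32, 0.74 and 0.52. On log2(TPM + 1) there were 3863 genes for LINC00704 ASO 2, 1235 for both, 5643 for ASO 2 against ASO 1, 4371 alike for LINC01116, and correlations of 0.27, 0.89 and 0.48. On log2(TPM + 0.1) there were 930 for both LINC00704 ASOs, 5466 for ASO 2 against ASO 1, 307 and 4221 alike, and correlations of 0.31, 0.84 and 0.47. For LINC01116 both, ZC3H13 reversed to −0.62 and −0.83 on these scales and AKR1C1 to −0.37 and −0.40.

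Leaving LINC00704 ASO 2 replicates 2 and 3 out, also chosen after seeing the data, left 1 library in that group, assumed to vary like the others. It gave 28 genes for ASO 2, 965 for both, 1548 for ASO 2 against ASO 1, 13 alike, 8 lists between the lncRNAs, correlations of 0.21 between the LINC00704 ASOs and 0.44 between the lncRNAs, and a LINC00704 change of −1.51 with ASO 2 (adjusted p = 0.0877). Both ASOs as 1 group of 6, likewise chosen after, counts the difference between ASOs as spread. It gave 519 genes for LINC00704, 2898 between the lncRNAs, a LINC00704 change of −2.20 (adjusted p = 0.0525) and a correlation of 0.56. With only the groups compared it gave 0 genes by edgeR for LINC00704, 2385 between the lncRNAs, −2.21 (adjusted p = 0.188) and 0.54.

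With a block for the replicate number, 5 genes were called for LINC01116 ASO 2 against ASO 1, and the other counts of whole comparisons stayed within 1.5 times. Deviations of libraries with the same number correlated at −0.16 to 0.14 over 30 pairs (mean 0.02), 5 of them over 0.1, and the library of the same number was the best match in 12 of the 30, so the numbers do not pair the libraries.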

Other observations

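The tests named in this part were chosen after the result was seen.

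BCYRN1, a small brain cytoplasmic RNA gene with many Alu-derived relatives in the genome, took 25.32 to 26.01% of TPM in the control, 10.99 to 14.15% with LINC00704 ASO 1, 26.5 to 31.1% with LINC00704 ASO 2 and 33.9 to 36.1% in the libraries labelled LINC01116 ASO. Its share of estimated reads lay between 0.48 and 2.63%.

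The median gene variance on the log2 scale was 0.0193 in the control, 0.0185 and 0.0571 with LINC00704 ASO 1 and ASO 2, and 0.0191 and 0.0242 in the LINC01116 groups (8828 genes). The first principal component of 1000 genes held 42.7% of variance and the second 10.9%. Transcripts with at least 10 CPM in every control library and 0 in every library of a group numbered 2 and 4 with LINC00704 ASO 1 and ASO 2 and 125 and 132 in the LINC01116 groups, 82 of them in both.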
